A study of Arabidopsis thaliana with 14 samples.

How the data were processed

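Transcript levels were measured with 1-colour whole-genome Arabidopsis arrays in 14 samples of total RNA from seedlings at 7 dpg, an age taken from the labels. The groups read from the labels were yda seedlings (4 arrays), seedlings with an N-terminal deletion form of YDA, here NdelYDA (4 arrays), a control line in the C24 ecotype (3 arrays) and a Ler ecotype control (3 arrays). The labels call the mutant samples biological replicates. The control labels carry only a number, so p-values involving them measure the spread between these samples, which may be partly technical.

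The deposited values are probe set signal intensities on a linear scale, per the file's own values. The mean of each array without its lowest and highest 2% of probe sets was 500, which is how a global scaling to 500 leaves the values. The software that made the intensities and any further step are not given in the sources used here. No detection calls were used. The file held 22810 probe sets, and the 64 array control probe sets were left out of the tests. Of the others, 13513 had 1 gene in the probe table used, 503 had several genes and 8730 were unnamed there. No gene was named from a probe set with several genes. Entrez identifiers matched 13436 of the 13513 to locus tags and symbols of the TAIR10.1 gene table, which was used for names only, and no coordinates are given. No 2 arrays held identical values.

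Values were tested as log2(intensity + 16). Log2 changes and folds are on that scale, which understates the change of genes with low signal. Probe sets were kept where the intensity exceeded the array's 30th percentile on at least 3 of the 14 arrays, which left 17210. The array medians lay within 0.14 log2 units, under the 0.3 set as the limit for quantile normalization, so the deposited scaling was kept. One linear model with 4 group means was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow an intensity trend. Each comparison was two-sided with Benjamini-Hochberg adjustment over the 17210 probe sets, and an adjusted p under 0.05 was a call. Counts with a fold of at least 2 are given too. The comparisons were NdelYDA against the Ler control, yda against the C24 control, the Ler against the C24 control, and the difference of the mutant effects, (NdelYDA minus Ler) minus (yda minus C24). The labels give the Ler ecotype for some NdelYDA samples and give no ecotype for yda. Pairing yda with C24 was therefore read from the design. The mutant comparisons share no control array. Overlaps of their calls were set beside n1 × n2 / N.

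Gene lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, on 9420 genes with 1 probe set each (the one with the highest mean). Of 17 lists with 378 genes fixed before the data were examined, 47 genes had a probe set of their own in the probe table and 42 passed the filter. The tests covered the 8 lists with at least 3 such genes, so each rests on a small part of its list. A further 28 lists of gene families and groups were written after the probe table, array correlations and control probe values had been seen but before any comparison was computed, and were adjusted separately. Their members came from symbol patterns or from memory of published loci, and were not checked against a source. Changes are described for the fixed lists and for the added lists named in the text.

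The rule for named genes was fixed before the data were examined. Among probe sets of 1 gene it took, for each mutant comparison, the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a fold of at least 2 and no overlap between arrays. It added every called stomatal lineage and guard cell list member, and up to 3 genes with the smallest p from each other fixed list past the camera threshold. For the ecotype comparison and the difference of effects it took the 6 largest each way, with non-overlap not asked of the difference. It took up to 10 genes called in opposite directions in the mutants, by the smaller of their changes. YDA, TMM, SDD1, FAMA and ER were to be given always, but of these the probe table used named a probe set only for FAMA, and the others are not analysed here. Members of the added lists are examples chosen after their values were seen.

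The scripts were tested on simulated data with 200 probe sets changed among 17210. For yda against C24, 86.6% of 2-fold changes and 55.2% of 1.5-fold changes were recovered, with 4.17% of calls false. For NdelYDA against Ler, the shares were 95.5% and 59.7%, with 6.63% false. For Ler against C24 they were 88.1% and 58.2%, with 6.32% false. For the difference of effects they were 73.1% and 44.8%, with 6.45% false. In 100 simulations of the list test, a list of 9 genes raised 1.5-fold in yda was found each time, and 8 of 1600 unchanged lists were called. The simulated noise was independent between genes, and far fewer probe sets were changed than were called in the data. Most fixed lists tested held 3 or 4 genes. These rates may therefore not carry over to the data.

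Alternatives were a pseudocount of 1 or 64, quantile normalization, median scaling, no filter or a 50th percentile filter, no variance trend, robust variances, array weights, the label number as a block, only the arrays compared, each array left out, only probe sets without shared sequence, other controls, and the other list tests. The added lists, the list tests without C24 replicate 1 and the other controls for named genes were chosen after the data had been seen. Other controls set a mutant wholly or partly against the other ecotype, so those changes also hold the difference between ecotypes. Marker lists for the core hypoxia response and the LEA family were written from memory after the largest changes had been seen.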

Results

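YODA (YDA) is a mitogen-activated protein kinase kinase kinase that restrains entry into the stomatal lineage of the leaf epidermis. The series compared seedlings with loss of YDA function (yda) and with gain of function through an N-terminal deletion form (NdelYDA) against ecotype controls, so the question was which transcripts follow YDA activity. Some NdelYDA labels describe the seedlings as without stomata. Each group held 3 or 4 arrays of whole seedlings at 7 dpg, with 22810 probe set intensities per array. Correlations of log2 intensities between arrays of a group were 0.983 to 0.988 in yda, 0.988 to 0.989 in NdelYDA, 0.987 to 0.989 in the Ler control and 0.977 to 0.985 in the C24 control. The GAPDH 3′ to 5′ signal ratio, one index of RNA integrity, was 0.864 ± 0.08 (SD, n = 4) in yda and 1.2 ± 0.23 (n = 3) in C24, and differed between them (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow). In C24 replicate 1 it was 1.458, against 1.123 and 1.018 in the others. The ratios of the other 4 control pairs (Actin and ubiquitin) overlapped between yda and C24, so the difference rests on GAPDH alone. In NdelYDA it was 1.07 ± 0.101 (n = 4) against 1.09 ± 0.0346 (n = 3) in Ler (exact permutation p = 0.8). The levels of YDA itself are not analysed here.

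Some of the tested genes that act in stomata had less transcript in seedlings with NdelYDA, and others were not called. SPCH, the bHLH factor that starts the stomatal lineage, was at 32.2 ± 13.4 (SD, n = 4) against 122 ± 18.2 (n = 3) in the Ler control. FAMA (FMA in the gene table), the bHLH factor of guard cell fate, was at 85.1 ± 11.3 against 254 ± 6.49. AT1G22690, whose promoter is active in guard cells, stood at 347 ± 49.9 against 2597 ± 83.3, and CHX20, a guard cell cation/proton exchanger, at 17.8 ± 14.4 against 137 ± 49.1. In NdelYDA, SPCH (20 to 50.9) and CHX20 (5.1 to 38.3) lay below the 30th percentile of each array (75.1 to 81.3), a low signal. The largest rise on the log2(intensity + 16) scale was that of PDF1.2b, a plant defensin, at 1652 ± 164 against 69.2 ± 20.7. Its probe set is of the type with shared sequence, so the signal may not be that of PDF1.2b alone.

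The log2 change was -1.55 for SPCH (SE 0.24, adjusted p = 0.00011) and -1.42 for FAMA, listed as FMA (SE 0.15, adjusted p = 1.6e-06). It was -2.86 for AT1G22690 (SE 0.16, adjusted p = 1.7e-09) and -2.22 for CHX20 (SE 0.31, adjusted p = 3.3e-05). STOMAGEN, a secreted peptide that promotes stomatal development, was at 994 ± 61.3 against 953 ± 38, and its log2 change of 0.06 (SE 0.15) was not called. Of the 4 tested stomatal lineage regulators, 2 fell and 2 were not called, and the same count came out adjusted over the list alone. As a list they did not pass the camera test (adjusted p = 0.0625). Among 3 tested guard cell genes, 2 fell, also adjusted over the list alone, and AT2G16630, a gene of the stomatal outer ledge, was not called at 442 ± 35.5 against 397 ± 11. That list passed camera (adjusted p = 0.0269), but not with an estimated correlation (adjusted p = 0.151). An added guard cell list of 5 genes had 4 that fell, by both adjustments, among them AT4G14480, a blue-light signalling kinase of guard cells, at 59.3 ± 6.72 against 210 ± 21. Its adjusted p was 0.00226, and 0.0818 with an estimated correlation. This added list is not independent of the fixed one, since its median change in yda (1.3) was that of AT1G22690.

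**Figure D1:**
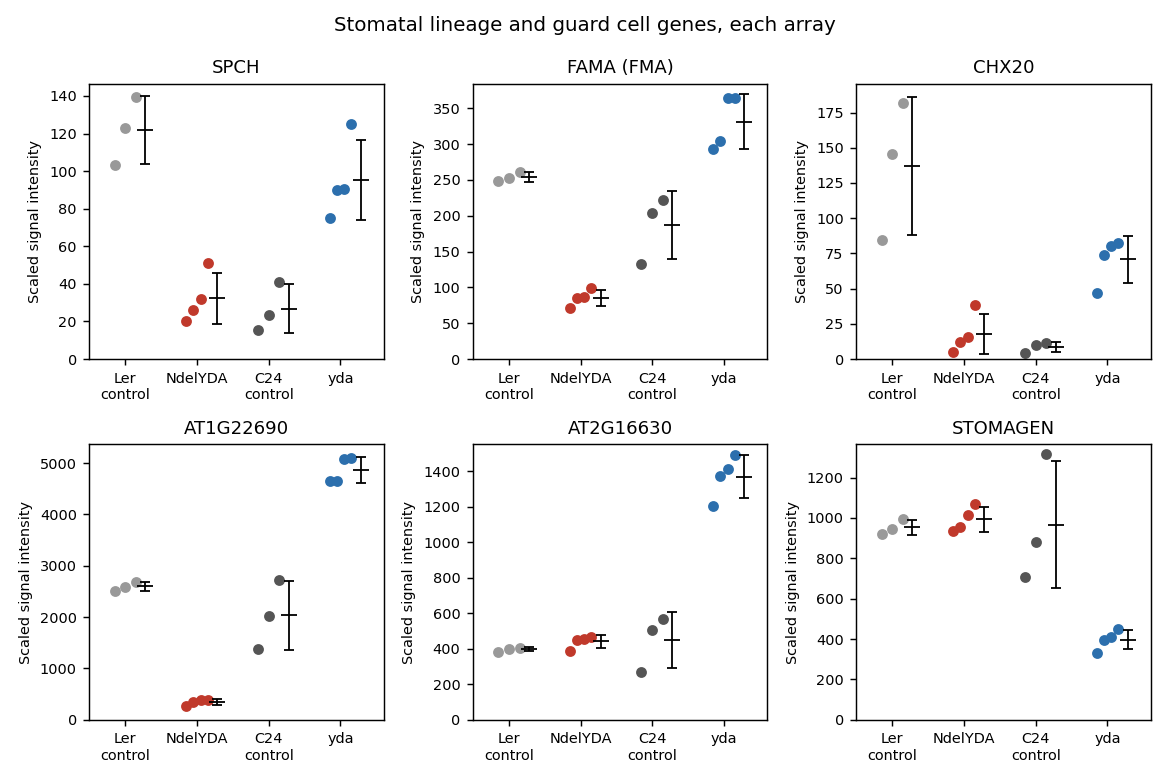
Scaled signal intensity (linear axis from 0) of 6 stomatal lineage and guard cell genes on each array, with the mean and SD of each group (n = 3 for the controls, n = 4 for the mutants). SPCH, FAMA, CHX20 and AT1G22690 lie below the Ler control in every NdelYDA array and above the C24 control in every yda array, while the STOMAGEN change in NdelYDA (0.06) was not called.

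Several defence transcripts rose in NdelYDA. Beside PDF1.2b (log2 change 4.32, SE 0.21, adjusted p = 2.5e-10), the largest rises were those of PDF1.4, another defensin (3.85), AT2G43620, of the chitinase family (3.94), M10, a late embryo protein (3.93), and AT1G65500 (3.57). AT5G52760, AT5G50335 and AT3G48640 followed at 3.47, 3.23 and 3.19. Against C24 in place of Ler, AT5G52760 (0.32, adjusted p = 0.0936) and AT3G48640 (-0.19, adjusted p = 0.498) were not called, so their rises rest on the Ler control. C24 is another ecotype, so changes against it also hold the difference between the ecotypes. The other largest rises named here kept their calls. M10 reached 298 ± 24.5 in NdelYDA and was below 9 on average in each other group, as 4.67 ± 2.63 in Ler. The salicylate and immune defence list passed camera (adjusted p = 0.00758), and its adjusted p was 0.0521 with an estimated correlation. WRKY53, a factor of defence and senescence, rose by 2.11 (SE 0.14), and BIK1, an immune receptor-associated kinase, by 0.39 (SE 0.081). Against C24 in place of Ler, BIK1 was not called (0.06, adjusted p = 0.55), so its rise rests on the Ler control. In C24, WRKY53 was at 191 ± 15.5, below the 342 ± 7.02 of NdelYDA, and WRKY22 at 609 ± 115, above its 346 ± 17.3. WRKY22 changed by 0.32 (adjusted p = 0.12) and passed when the list was adjusted alone, so that 2 of 3 members were called over all probe sets and 3 of 3 adjusted over the list alone. Defensin-like peptides, an added list, had 5 of 8 members higher and 1 lower, and 6 called over the list alone (adjusted p = 0.00226, and 0.0818 with an estimated correlation). Among xyloglucan endotransglucosylases, enzymes that remodel the cell wall, 5 of 7 rose and XTH21 fell by 2.61, with 6 called over the list alone (list adjusted p = 0.00427, and 0.0818 with an estimated correlation). In yda, 4 of the 7 rose and 1 fell (list adjusted p = 0.0316, and 0.283 with an estimated correlation).

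All 3 tested anthocyanin and flavonoid genes rose, over all probe sets and adjusted over the list alone. The list passed camera (adjusted p = 0.00226), but not with an estimated correlation (adjusted p = 0.0903). DFR, dihydroflavonol reductase, was at 420 ± 17.3 (n = 4) against 127 ± 15.8 (n = 3). AT4G14090, an anthocyanin glucosyltransferase, was at 91.9 ± 25.5 against 7.23 ± 2.06, and UF3GT rose by 0.61 (SE 0.17, adjusted p = 0.013). UF3GT missed the threshold without replicate 1 of Ler (adjusted p = 0.0735), without replicate 3 of Ler (0.0689) and against C24 in place of Ler (0.262). All 3 tested auxin genes fell by both adjustments, and this list passed with a preset (adjusted p = 0.00133) and an estimated correlation (adjusted p = 0.0319). Without C24 replicate 1 in the fit, the auxin list missed the threshold with an estimated correlation (adjusted p = 0.0577). IAA29, an auxin-induced repressor, was at 113 ± 13.9 against 330 ± 33.9. GH3.3, an auxin-conjugating enzyme, fell by 0.86 and the related WES1 by 0.79. Against C24 in place of Ler, GH3.3 was not called (-0.20, adjusted p = 0.128), while IAA29 and WES1 kept their calls. Class III peroxidases split, with 21 of 42 lower and 8 higher and 31 called over the list alone, from a fall of 2.19 for AT1G34510 to a rise of 2.98 for PRX52 (list adjusted p = 0.00464, and 0.26 with an estimated correlation). The 9 tested photosynthesis genes held 1 that rose and 2 that fell, 3 adjusted over the list alone, and did not pass as a list (adjusted p = 0.638). The abscisic acid, cold and water stress list (adjusted p = 0.821) and the glucosinolate list (adjusted p = 0.978) did not pass either.

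Among probe sets of 1 gene, the largest fall was that of AT5G04120, from 1514 ± 37.3 in Ler to 17.2 ± 5.65 in NdelYDA. It was followed by AT1G52820, an oxoglutarate-dependent dioxygenase (-3.35), AT2G19970 (-3.21), hemb2 (-2.95), AT1G22690 (-2.86), AT1G14960 (-2.85), AT2G33850 (-2.81) and AT5G25840 (-2.67). Against C24 in place of Ler, hemb2 was higher in NdelYDA (0.56, adjusted p = 0.00632), so its fall rests on the Ler control. Across the array, 5503 of 17210 probe sets were called, 2646 higher and 2857 lower, or 2895 and 2554 with each array scaled to the same median. With a fold of at least 2 these were 473 and 572. Of the 5503, 2803 had 1 gene in the probe table used. With a pseudocount of 64 the count at a fold of at least 2 was 693 in place of 1045.

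In yda seedlings, the 3 tested guard cell genes had more transcript than in the C24 control. AT1G22690 was at 4867 ± 255 (SD, n = 4) against 2035 ± 677 (n = 3), AT2G16630 at 1369 ± 121 against 449 ± 157, and CHX20 at 70.9 ± 16.6 against 8.6 ± 3.8. SPCH was at 95.1 ± 21.3 against 26.7 ± 13, and FAMA (FMA) at 332 ± 38 against 187 ± 47.3. In C24, SPCH (15.5 to 41) and CHX20 (4.3 to 11.5) lay below the 30th percentile of each array (76.2 to 85.75). CHX20 also lay below it in every yda array but replicate 4. Outside yda, CHX20 exceeded it only in Ler replicates 1 and 3, so it passed the filter on the minimum of 3 arrays. With any of these left out, CHX20 was not tested, so the guard cell list fell under the 3 genes a list test needs. STOMAGEN was lower, at 397 ± 48.3 against 968 ± 313. C24 replicate 1, the array with the highest GAPDH ratio, was the lowest C24 array for AT1G22690, AT2G16630, CHX20, SPCH and FAMA and the highest for STOMAGEN, and without it the median change of the guard cell list was 1.32 in place of 1.64. The largest rise on the log2(intensity + 16) scale, among probe sets of 1 gene, was that of AT4G12500. This lipid transfer-like protein gene was at 2653 ± 505 against 69.1 ± 26.2.

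All 3 tested guard cell genes rose by both adjustments, with log2 changes of 1.81 for CHX20 (SE 0.31, adjusted p = 0.00017), 1.64 for AT2G16630 (SE 0.17, adjusted p = 1.4e-06) and 1.30 for AT1G22690 (SE 0.16, adjusted p = 8.3e-06). The list passed camera (adjusted p = 0.00536), though not with an estimated correlation (adjusted p = 0.136). In the added guard cell list, 4 of 5 genes rose and AT5G06970 fell by 0.26, all 5 also called over the list alone (list adjusted p = 0.0323, and 0.386 with an estimated correlation). Its median of 1.3 was the change of AT1G22690, so it overlaps the fixed list and gives no independent support. The stomatal lineage regulators did not move one way as a list (camera adjusted p = 0.895). SPCH rose by 1.4 (SE 0.24, adjusted p = 0.0002), FAMA (FMA) rose by 0.80 (SE 0.15, adjusted p = 0.00038) and STOMAGEN fell by 1.21 (SE 0.15, adjusted p = 7.8e-06), while ATBRXL2 was not called at 78.6 ± 18.8 against 99.1 ± 5.67. These 3 were also the number called adjusted over the list alone.

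Genes of cytosolic ribosomal proteins rose together in yda. Of 112 tested members of this added list, 99 were called higher and none lower by limma, 102 were called over the list alone, and all 112 had a positive change. The median log2 change was 0.38, against -0.03 for all genes, and single members ran from 0.07 to 1.2. AT5G39850 rose most, by 1.2 (SE 0.0969). The list passed camera with a preset correlation (adjusted p = 1.13e-26) and with an estimated one (adjusted p = 0.00646). Its median was 0.34 after quantile normalization and 0.45 after median scaling. In NdelYDA, 19 of the 112 rose, 12 were called over the list alone, the median was 0.07 and the adjusted p was 0.00226, or 0.235 with an estimated correlation. The difference between the mutants had an adjusted p of 9.9e-14, and 0.0705 with an estimated correlation.

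Several defence transcripts also rose in yda. All 3 tested members of the salicylate and immune defence list rose by both adjustments, and the list passed with a preset (adjusted p = 0.00287) and an estimated correlation (adjusted p = 0.0385). WRKY53 was at 601 ± 122 against 191 ± 15.5, WRKY22 at 1540 ± 351 against 609 ± 115, and BIK1 at 1360 ± 38.3 against 811 ± 81.4. PDF1.2b, read by a probe set with shared sequence (log2 change 4.18), and AT2G43620 (3.74) were among the 8 largest rises, as in NdelYDA. The others were AT4G12500 (5.0, SE 0.18, adjusted p = 1.6e-11), AT5G10040 (4.18), AT4G33560 (4.09), AT4G12490 (3.96), AT3G16670 (3.74) and AT2G38240, an oxoglutarate-dependent dioxygenase (3.67). Other defence genes fell in yda, among them PDF2.1 (log2 change -1.78), AT2G43590 (-2.30) and the thionin gene AT1G66100 (-2.09). The defensin-like peptides had 3 of 8 members higher and 4 lower, with 7 called over the list alone, and did not pass (adjusted p = 0.647). With median scaling 2 of them were lower. Of an added list of calmodulin-like and wound response genes, 10 of 19 rose and 2 fell in yda, with 14 called over the list alone (adjusted p = 0.00202, and 0.239 with an estimated correlation). In NdelYDA 9 rose and 4 fell, with 14 called over the list alone (adjusted p = 0.00291, and 0.0857 with an estimated correlation). The nuclear photosynthesis genes of a further added list fell in 9 of 12 cases, with 10 called over the list alone (5 lower and 1 higher with median scaling; adjusted p = 0.0144, and 0.494 with an estimated correlation). The fixed photosynthesis list, with 6 of 9 lower and 7 adjusted over the list alone, missed the threshold (adjusted p = 0.055). With median scaling 3 were lower and 1 higher, and without C24 replicate 1 the photosynthesis list passed (adjusted p = 0.0197, and 0.515 with an estimated correlation). The threshold was also missed by the abscisic acid, cold and water stress list, with 3 of 4 lower by both adjustments (adjusted p = 0.0577). Neither the auxin list (adjusted p = 0.895) nor the anthocyanin and flavonoid and the glucosinolate lists (0.911 for both) passed.

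Among the largest falls, AT1G52820 went from 483 ± 167 to 47.5 ± 11.9 and AT2G33850 from 403 ± 60 to 47.7 ± 4.4. Further down were AT3G45710 (-2.62), AT1G67870 (-2.58), AT4G01390 (-2.38), AT2G20670 (-2.30), the chitinase family gene AT2G43590 (-2.30) and EXPA8, an expansin (-2.30). In total 7470 probe sets were called, 3279 higher and 4191 lower, or 3982 and 3425 with median scaling. With a fold of at least 2 the numbers were 473 and 636. Against the Ler control in place of C24, the count at a fold of at least 2 was 2584 in place of 1109, and with a pseudocount of 64 it was 720. Without replicate 1 of C24, which stood apart from the other C24 arrays, 7002 probe sets were called.

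The control ecotypes differed widely, which matters for any gene compared across backgrounds. AT1G66100, a thionin gene, was at 7692 ± 646 (SD, n = 3) in C24 and 32.5 ± 2.99 (n = 3) in Ler. AOP3, a glucosinolate side-chain enzyme, was at 28.6 ± 10.5 in C24 and 1379 ± 53.4 in Ler. SPCH and CHX20 also differed, with Ler above C24 by 1.73 (SE 0.26, adjusted p = 6.6e-05) and 2.60 (SE 0.33, adjusted p = 1.2e-05) on the log2 scale.

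The other large differences in favour of Ler were AT5G47980, of an acyltransferase family (6.28), AT1G23960 (4.46), hemb2 (3.51), AT2G14460 (3.49) and ATCES1 (3.38), beside AOP3 (5.0). In favour of C24 were AT1G66100 (-7.31), AT1G52100, a jacalin-type lectin (-5.85), AT2G25510 (-5.50), AT2G25450 (-5.36), AT4G29200 (-5.0) and AT1G61500 (-4.87). FAMA (FMA) was higher in Ler by 0.44 (SE 0.16, adjusted p = 0.037), and this call was lost without replicate 1 of C24 (0.24, adjusted p = 0.181) and in 8 other alternatives. The 3 salicylate and immune defence genes were lower in Ler by both adjustments (list adjusted p = 0.0141, and 0.0812 with an estimated correlation). Of the calmodulin-like and wound response genes, 12 of 19 were lower and 2 higher, with 15 called over the list alone (adjusted p = 3.69e-05, and 0.0641 with an estimated correlation). In all, 6399 probe sets were called, 3617 higher and 2782 lower in Ler, or 2892 and 3180 with median scaling. Of these, 487 and 708 had a fold of at least 2, or 791 in place of 1195 with a pseudocount of 64. A sequence difference under a probe can lower its signal without a change of transcript level, and 3 arrays against 3 limit the comparison.

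Some genes moved oppositely in the mutants, among them 2 of 4 tested stomatal lineage regulators, 2 of 3 guard cell genes and M17, a late embryo protein gene. CHX20, AT1G22690, SPCH and FAMA (FMA) fell in NdelYDA and rose in yda. With the controls exchanged, SPCH changed by 0.18 in NdelYDA (adjusted p = 0.57) and -0.32 in yda (0.264). CHX20 changed by 0.38 (0.332) and -0.79 (0.0363). The exchange adds the ecotype differences of these genes given above to the mutant changes. The opposite directions of SPCH and CHX20 thus rest on the pairing of mutants with controls, while AT1G22690 and FAMA kept theirs. AT1G33811, a lipase family gene, was at 268 ± 42.3 in NdelYDA against 1523 ± 114 in Ler, and at 4117 ± 579 in yda against 983 ± 188 in C24. AT3G62820 fell by 1.91 in NdelYDA and rose by 1.82 in yda. M17 was at 1503 ± 75.1 in NdelYDA against 391 ± 50.2 in Ler, and at 141 ± 30.9 in yda against 805 ± 561 in C24.

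In the same direction as M17 went AT2G28490, a cupin family gene, AT3G21380, AT2G15010, PDF2.1, AT5G60760 and AT2G43590, with rises in NdelYDA from 1.98 for AT2G28490 to 2.70 for AT2G43590. Their falls in yda ran from 1.74 for AT2G15010 to 2.30 for AT2G43590. With the controls exchanged, AT2G43590 turned in both mutants (-0.84 in NdelYDA, 1.24 in yda), AT5G60760 was called in neither (0.31, adjusted p = 0.413, and -0.21, adjusted p = 0.558) and AT2G28490 was not called in NdelYDA (0.78, adjusted p = 0.0727). AT2G28490 was at 1395 ± 1170 (SD, n = 3) in C24, where replicate 1 stood apart from the other C24 arrays. The spread in C24 was also wide for PDF2.1 (385 ± 259), AT2G15010 (309 ± 216), AT3G21380 (699 ± 378) and AT5G60760 (87.8 ± 46.2). It was narrower for AT2G43590 (2466 ± 386). Of all probe sets, 1067 were called in both mutants in opposite directions, 670 higher in NdelYDA and lower in yda and 397 the reverse, where 1189 would be called if the lists were independent. Another 2233 were called in the same direction, against 1200 for independent lists. Across the 17210 probe sets, the changes in the mutants correlated with a Pearson r of 0.32 and a Spearman rho of 0.224. Probe sets are not independent replicates.

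**Figure D2:**
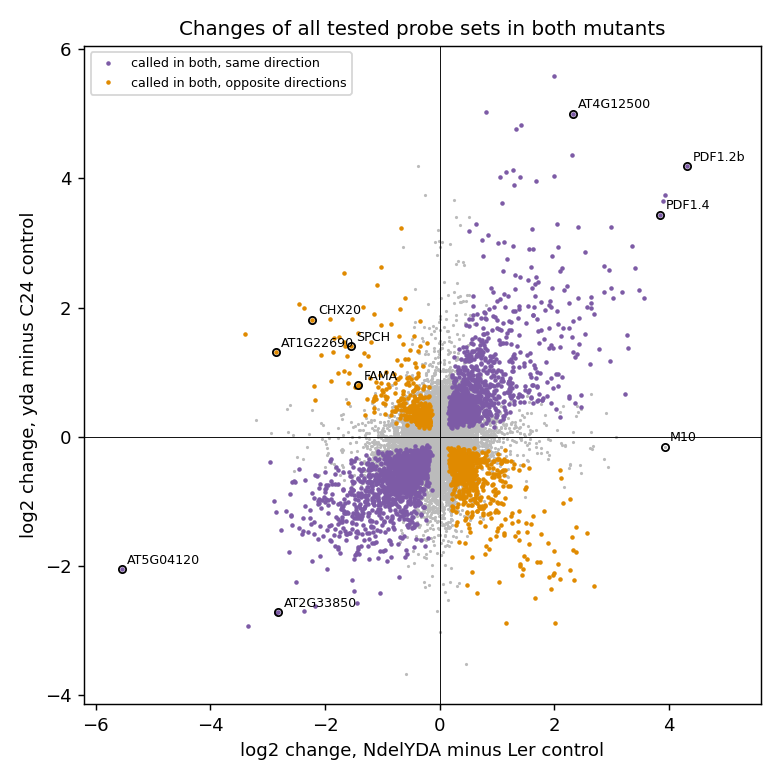
Log2 change in NdelYDA (minus Ler control, horizontal axis) against log2 change in yda (minus C24 control, vertical axis) for the 17210 tested probe sets, with those called in both mutants coloured by direction. The same-direction probe sets (2233) outnumber those with opposite directions (1067), and CHX20, AT1G22690, SPCH and FAMA lie in the upper left.

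The difference of the mutant effects, (NdelYDA minus Ler) minus (yda minus C24), was tested directly. AT1G22690 had a difference of -4.16 (SE 0.23, adjusted p = 4.5e-09), CHX20 of -4.03 (SE 0.43, adjusted p = 3.6e-06), SPCH of -2.95 (SE 0.34, adjusted p = 7.4e-06), and FAMA (FMA) of -2.23 (SE 0.21, adjusted p = 1.1e-06). With the controls exchanged, SPCH and CHX20 changed sign in both mutants, but of these only CHX20 in yda was called (adjusted p = 0.0363). Their differences thus also rest on the pairing of mutants with controls. STOMAGEN had a difference of 1.27 (SE 0.21, adjusted p = 0.00024). The largest positive differences were those of AT2G43590 (5.0), which turned in both mutants with the controls exchanged and had a difference of -3.54 between Ler and C24, and AT3G21380 (4.56), then PDF2.1 (4.15), AT2G28490 (4.11), M10 (4.08) and M17 (4.08). The largest negative ones, beside AT1G22690 and CHX20, were AT5G10040 (-4.56), AT1G33811 (-4.50), AT1G75880 (-4.20) and AT3G16670 (-3.99).

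All 3 tested guard cell genes differed by both adjustments, with a median of -4.03, the value of CHX20 (camera adjusted p = 0.000463, and 0.105 with an estimated correlation). The auxin list had 1 of 3 members called, GH3.3, at -2.59, and 2 adjusted over the list alone (camera adjusted p = 0.0231, and 0.108 with an estimated correlation). GH3.3 was at 1196 ± 78.2 in yda against 348 ± 47.6 in C24. The anthocyanin and flavonoid list was relatively higher in NdelYDA, with 2 of 3 called and 3 adjusted over the list alone (camera adjusted p = 0.0182, and 0.165 with an estimated correlation). A total of 5753 probe sets differed, 3034 with the higher effect in NdelYDA and 2719 with the higher effect in yda, or 2744 and 3022 with median scaling. With a fold of at least 2, the counts were 787 and 534. Each difference carries the errors of 4 groups, and its median SE was 0.166 against 0.117 for a mutant comparison.

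**Figure D3:**
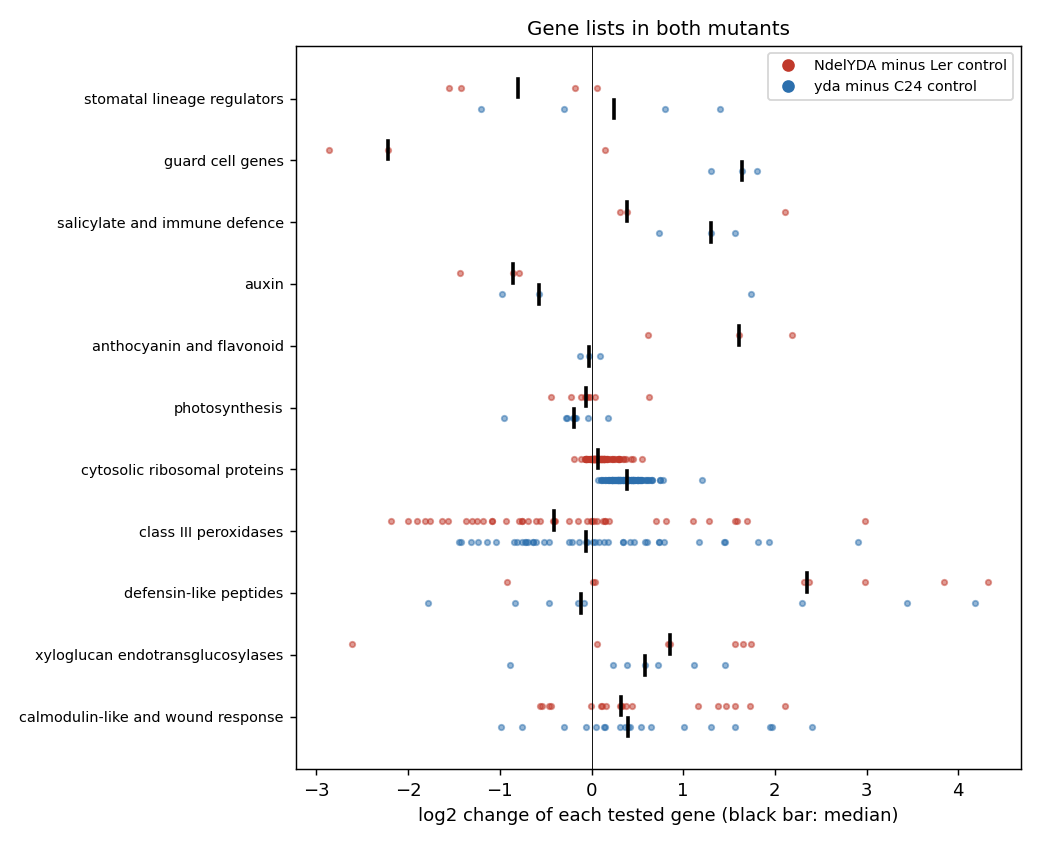
Log2 change of every tested gene (points) of 11 gene lists in NdelYDA (minus Ler control) and in yda (minus C24 control), with black bars at the medians. The ribosomal protein genes lie above 0 in yda in all 112 cases, and the guard cell genes have medians of -2.22 in NdelYDA and 1.64 in yda.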

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

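The tests on the RNA integrity of C24 replicate 1, on array scaling, on the growth conditions of yda and on seed tissue, with its repeats on fewer genes, were chosen only after the results were seen. The tests on LEA and hypoxia genes not looked at before were written before those values were seen.

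Within NdelYDA, replicate 2 lay far from the other 3 arrays for a pair of named genes. AT1G65500 was at 1256 against 1406 to 1426 in the others, a gap of 0.882 of the group's range. AT2G20670 was at 3680 against 4151 to 4158, a gap of 0.986 of the range. Over the 124 groups of 4 arrays examined, chance alone would give about 6.2 such cases. Among control probe sets outside the comparisons, the GAPDH 5′ probe set was 1.58-fold higher in yda, at 6175 ± 320 (SD, n = 4) against 3914 ± 701 (n = 3) in C24, with every yda array above every C24 array. The minimum of 1.5-fold for naming such a probe set was set after control values had been seen.

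C24 replicate 1 stood apart from the other C24 arrays. Degraded RNA would raise the 3′ to 5′ ratio of the control transcripts, and in 4 of 5 pairs this ratio was highest in replicate 1 of the C24 arrays, with the remaining pair (Ubq) at 2.009 against 2.023 in replicate 3, so this stays open. A different content of late embryo transcripts may also set it apart, since 81.8% of 11 LEA genes not looked at before were highest in replicate 1. Apart from that content, no biological explanation was tested, because the labels give all 3 arrays as one group. The number of called probe sets in yda was 7002 without it, in place of 7470. Of all pairs of a mutant array and its control, C24 replicate 1 and yda replicate 4 deviated most alike (r = 0.322). For GAPDH and 1 ubiquitin pair (r2Ubq, 1.745 and 1.712) both had the highest ratio of their group. For neither Actin pair was yda replicate 4 the highest of its group. Why these arrays deviated alike was not tested.

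Genes of the core hypoxia response were higher in yda than in C24, with 15 of 21 tested members called higher and none lower by limma. Among the 14 members not looked at before, 8 were called higher and none lower. The 14 members not looked at before had a median log2 change of 0.58, above all 10000 random lists matched on level (percentile 100, with the 99th percentile at 0.224). The rise was thus not limited to the largest changes looked at. Random genes were drawn singly, while members of 1 response may move together, so the percentile does not exclude chance. Array scaling is argued against by the excess of 1.36 of the list's median over that of all probe sets, and by the 0.58 of the members not looked at before against -0.03 for all probe sets. In 4 of 4 yda arrays the list mean lay above every C24 array, and growth or harvest conditions shared by the yda seedlings cannot be told apart from their genotype. An effect of the yda genotype remains an untested possibility.

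Of 15 tested LEA genes of the late embryo, 10 rose and 2 fell in NdelYDA against Ler, and 13 fell and 1 rose in yda against C24. The controls differed too, with 9 lower in Ler than in C24 and none higher (median -0.90, against 0.99 for the NdelYDA change), and the NdelYDA array means (7.953 to 8.059 log2) lay within those of C24 (7.546 to 8.317), so the rise in NdelYDA rests on the Ler control. For the 11 genes not looked at before, the median difference of effects was 1.84, above all 10000 matched random lists (percentile 100, with the 99th percentile at 0.352). The difference was thus not limited to the genes looked at. These random genes were also drawn singly, so chance is not excluded. Whether seeds or seed tissue in some harvests may contribute stays open, since the NdelYDA change and the excess of C24 replicate 1 had a Pearson r of 0.688 across these 15 genes, which are not independent, but 0.395 without AT5G60530 and 0.816 over the 11. M10 was at 298 ± 24.5 (SD, n = 4) in NdelYDA but 8.73 ± 2.25 (n = 3) in C24, and an effect of YDA activity stays open and untested.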

How the results depend on the processing

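Apart from those named above as chosen later, the alternatives were chosen before the data were examined. Among the 96 named gene results, 2529 of 2558 alternative values kept their direction and side of the threshold. Another 19 kept their sign but lost the call, and 2 for WRKY22 in NdelYDA gained one (array weights, only the arrays compared). The remaining 8 changed sign, whether called or not. Of those that lost it, 9 were FAMA between the ecotypes and 2 UF3GT with an array left out. All the others, and every change of sign, came with other controls. NdelYDA against C24 gave log2 changes of 0.181 for SPCH, 0.38 for CHX20, 0.562 for hemb2, -0.194 for AT3G48640 and -0.839 for AT2G43590, and yda against Ler gave -0.324 for SPCH, -0.787 for CHX20 and 1.24 for AT2G43590. Of these, SPCH in both mutants and CHX20 and AT3G48640 in NdelYDA were not called. The counts of called probe sets stayed within 1.5 times the reported ones in every alternative. With a fold of at least 2, a pseudocount of 64 gave 693, 720 and 791 probe sets for NdelYDA, yda and the ecotypes, and yda against the Ler control gave 2584. That last comparison also holds the difference between the control ecotypes, which alone gave 1195 probe sets at this fold. The share of the 2584 due to it was not tested. For NdelYDA, 4 lists became 2 with the 50th percentile filter and 1 with an estimated correlation. For yda, 2 lists became 4 with quantile normalization, no filter or fry, and 1 with only probe sets without shared sequence or an estimated correlation. Between ecotypes, 1 list became 0 with an estimated correlation and 5 with fry. For the difference of effects, 3 lists became 5 with quantile normalization, 0 with the 50th percentile filter or an estimated correlation, and 7 with fry. The cause was not tested. Leaving out each array gave 1 to 4 lists for yda, 4 without NdelYDA replicate 4 and 1 without Ler replicate 1 or 3. With the Ler omissions, the guard cell list was untested. Probe sets ranged from 4479 to 6021 for NdelYDA, 6684 to 7343 for yda, 5208 to 6568 for the ecotypes and 5046 to 5836 for the difference. Without C24 replicate 1, the NdelYDA auxin list lost its pass with an estimated correlation (0.0319 to 0.0577), and no list lost one with the preset. With an estimated correlation, passes were gained by guard cell genes in yda (0.136 to 0.0347) and, for the difference, by guard cell genes (0.105 to 0.0184), the extended guard cell list (0.0705 to 0.0182) and ribosomal proteins (0.0705 to 0.00429). With the preset, they were gained in yda by photosynthesis (0.055 to 0.0197), plastid-encoded photosynthesis (0.277 to 0.00081) and other plastid-encoded genes (0.362 to 0.00938), and for the difference by photosynthesis (0.0905 to 0.0307) and defensin-like peptides (0.0707 to 0.0133). None of these passed with an estimated correlation (in that order 0.515, 0.584 and 0.507 in yda, 0.345 and 0.232 for the difference). Median scaling turned the balance of directions in every comparison, with higher calls going from 48.1% to 53.1% in NdelYDA, 43.9% to 53.8% in yda, 56.5% to 47.6% between ecotypes and 52.7% to 47.6% for the difference.

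Same-numbered arrays of a mutant and its control did not deviate together, with correlations from -0.156 to 0.0845. The highest of any pair was yda replicate 4 with C24 replicate 1 (0.322). With the number as a replicate block, 5110 probe sets were called for NdelYDA, 7171 for yda, 6247 for the ecotypes and 5587 for the difference, and 4 lists for yda in place of 2.

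Other splits of the arrays gave fewer called probe sets. The real split was the 1 with the most of 35 for NdelYDA (5503, highest other 1420) and of 35 for yda (7470, highest other 3871). It was also the 1 with the most of 100 drawn for the difference (5753, highest other 2592). The share as large was under 0.05 in each, which shows that the groups differed but not why. Regrouped arrays gave no opposite calls (1 of 100 as large, 1067, highest other 0), which shows only that the groups differed, since the real count lies below the 1189 of independent lists. The 10 splits of the controls are too few for a share under 0.05 (6399, highest other 0, 1 as large). List counts left chance open in NdelYDA (4, highest other 4, 2 of 35 as large) and yda (2, highest other 3, 9 of 35). For the difference, the share (2 of 100, 3 against 3) shows only that groups differed. The 10 control splits (4 as large, 1 against 2) are too few.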

Other observations

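The test of the background of yda was chosen only after the result was seen. MUTE, the bHLH factor between SPCH and FAMA in the stomatal lineage, did not pass the filter on low signal and was not tested. Its intensities were 24.9, 32.5, 71.3 and 74 in the yda arrays, 4.4 to 5 in NdelYDA, 4.1 to 11.6 in C24, and 39.6, 6.3 and 5.4 in Ler.

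Of the genes of the core hypoxia response that were higher in yda, AT4G10270 was at 2550 ± 140 (SD, n = 4) against 252 ± 78 (n = 3) in C24, and PDC2, a pyruvate decarboxylase of fermentation, at 1680 ± 345 against 654 ± 77.7. AT4G10270 was also lower in Ler than in C24, with a log2 difference of -2.01. Plastid-encoded genes for photosynthesis were not called in most cases, with 5 of 45 lower in NdelYDA, 3 with quantile or median scaling and 1 over the list alone (list adjusted p = 0.00777, and 0.644 with an estimated correlation). In yda, 7 of the 45 were lower, and 4 were called over the list alone (list adjusted p = 0.277, and 0.811 with an estimated correlation). Tubulin genes had 3 of 7 lower and 1 higher in NdelYDA, with TUB1 at a log2 change of -0.998 (list adjusted p = 0.0189, and 0.0857 with an estimated correlation).

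The labels give no ecotype for yda. On 232 probe sets that differed by over 2 log2 units between C24 and Ler in replicates 1 and 2, the position of yda between replicate 3 of C24 (0) and replicate 3 of Ler (1) had a median of -0.00276, and that of NdelYDA a median of 0.87. An actin control probe set was at 1020 ± 171 (SD, n = 4) in yda and 1066 ± 41.4 (n = 3) in C24, but at 5417 ± 103 in NdelYDA and 5675 ± 284 in Ler.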
